A study of Mus musculus with 2 samples.

How the data were processed

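Single cells of the AGM region and yolk sac of E9.5 and E11.5 mouse embryos, sorted as VE-cadherin positive or negative and negative for 7AAD, a dye of dead cells, had been processed on 2 ICELL8 chips, 1 per stage, and sequenced together on a NextSeq 500. The deposited tables hold whole-number counts per gene and well, 1 table per chip; per the submitters' processing notes the authors checked reads with FastQC, trimmed them with cutadapt and mapped them with STAR to mm10 (GRCm38). Versions, the counting tool, the gene annotation and the use of molecular identifiers are not stated. The tables hold 20575 gene rows and 1378 wells at E9.5 and 20823 gene rows and 1576 wells at E11.5, with 9165446 and 5162906 counts in all; the 18323 gene rows present in both were used for the comparisons.

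Wells were grouped by the stage, tissue and gate given in the deposited tables into 8 sorted pools and the control wells of each chip. Wells with at least 500 genes and at most 20% mitochondrial counts were kept, 1283 at E9.5 and 1343 at E11.5. Depth was a median of 2538 to 12452 counts per well and 841341 to 3862642 counts per pool. Scrublet scores marked 8 (0.624%) and 7 (0.521%) wells as doublets; they were kept, and leaving them out was an alternative. Control wells entered no comparison of pools and served to measure haemoglobin RNA outside the sorted cells and differences between the chips.

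Counts were summed over the wells of a pool and divided by the pool's total (CPM). Pools were compared as log2 ratios of CPM with exact 95% intervals from the conditional binomial distribution, with 0 counts set to a floor of 3 counts per pool. Comparisons were positive against negative gate (4 pairs), AGM against yolk sac within each gate (2 stages) and E11.5 against E9.5 within each gate (2 tissues). Since each pool is 1 sample, no test across samples was made and no p-value is given. Named genes were chosen by a fixed rule: among genes that differ the same way in every pair, with at least 50 counts in the higher pool of every pair and a count in at least 10% of its wells, the 12 in each direction whose smallest ratio over the pairs was largest. Mitochondrial, ribosomal protein and unnamed genes were left out. Cdh5, Pecam1, Runx1, Gfi1, Gfi1b, Kit, Ptprc and Itga2b were chosen for report whatever their values, though not every pair is printed below. List members were reported as examples. For 36 gene lists (16 of cell types and 20 others) the median log2 ratio of members with at least 20 counts over the pair was set against 10000 random lists of genes of matching level (20 bins), with an interval from 1000 Poisson redraws; members at least 2-fold apart the same way in every pair, with at least 20 counts in the higher pool, were counted.

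Cell classes came from Leiden clusters made apart for each stage (2000 variable genes, 30 principal components, 15 neighbours, resolution 1). A cluster took the name of the cell type with most fixed markers among its 10 leading genes, if these were at least 2 and more than those of all other types together, and at least 3 of its markers were detected (in at least 10% of cells and at least 1.5 times the level outside the cluster). With no marker among the leading genes, the type with most detected markers (at least 3) gave the name; the rest stayed unnamed. Co-expression of the 8 transcription factors of the endothelial-to-haematopoietic transition was counted in wells thinned at random to 2000 counts, leaving out shallower wells. Processed pseudogene copies of 16096 protein-coding genes were sought among 10256 pseudogene transcripts with megablast (at least 200 aligned bases, at least 90% identity). On simulated counts with 200 genes set 2-fold or 4-fold apart, 24 of 24 named genes were right in each comparison. For the genes set 4-fold apart, the median recovered log2 ratio lay between 1.88 and 2.04, and intervals covered the true value for at least 92%. The simulated counts were Poisson draws, so this coverage need not hold for counts that include copies of the same molecule. Apart from the 200 genes, all simulated pools of a comparison shared 1 expression profile. The naming rule was thus not tried on pools that differ widely in composition, such as in their haemoglobin share.

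The gene lists, filters, naming rule of genes and most alternatives were fixed before the data were examined. Alternatives were no cell filter, a strict one (at least 1000 genes, at most 10% mitochondrial counts), equal weight per cell, TMM scaling, totals without haemoglobin and mitochondrial genes, doublets left out, named classes alone, each pair left out, list members with at least 100 counts, other clustering settings, no thinning, and 5 or 7 factors. Chosen after seeing the data were totals also without Gm42418 (a row of ribosomal RNA) and wells with at least 3 of the 12 endothelial markers. So were stage names of protein-coding genes without pseudogene copies or control differences. Software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, scikit-learn 1.9.0 and umap-learn 0.5.12, R 4.3.3 with edgeR 4.0.16, and BLAST+ 2.17.0.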

Results

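The data are counts of RNA-seq reads from single wells of 2 ICELL8 chips, a nanowell format in which each well holds 1 imaged cell. 1 chip carried cells of mouse embryos (C57Bl/6) at embryonic day 9.5 (E9.5) and the other carried cells at E11.5. Each chip held 4 sorted pools: cells of the aorta-gonad-mesonephros region (AGM), where definitive blood stem cells arise, and of the yolk sac, the extra-embryonic site of the earliest blood, each sorted as VE-cadherin positive (endothelial) or negative (the surrounding microenvironment). Every pool is 1 sample, so no replicates exist, no test was run, and all values below describe these 8 pools. Intervals are exact 95% intervals that cover counting error only; the counts may include copies of the same molecule, since the use of molecular identifiers is not stated.

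After filtering, the E9.5 chip gave 299 AGM positive, 354 AGM negative, 325 yolk sac positive and 305 yolk sac negative wells, with total counts of 1902499, 1699711, 1382810 and 3862642. The E11.5 chip gave 284, 337, 343 and 379 wells in the same order, with totals of 841341, 1090748, 1184049 and 1630507. Median counts per well were 5832, 4396, 3961 and 12452 at E9.5 and 2538, 2805, 3008 and 3842 at E11.5. Both chips also held positive control wells with RNA of E14FF mouse embryonic stem cells (46 wells with 310576 counts at E9.5, 47 wells with 149080 counts at E11.5) and negative control wells (48 wells with 6452 counts, 47 wells with 17289 counts). Median genes per well were 1831, 1814, 1504 and 2240 at E9.5 and 752, 1294, 777 and 1067 at E11.5, and median mitochondrial shares 3.07%, 4.00%, 3.51% and 2.80% against 7.05%, 5.85%, 5.58% and 4.42%. A strict filter would keep 296 of 299 AGM positive wells at E9.5 but 77 of 372 at E11.5, so well quality differs along with the stage. Haemoglobin genes took a median of 24.4%, 4.54%, 19.0% and 38.1% of a well's counts in the E9.5 pools and 25.6%, 3.44%, 34.8% and 31.5% in the E11.5 pools. All of the 2626 kept wells held haemoglobin counts, so a low count of an abundant gene in a well is not read here as expression by that cell.

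**Figure D1:**
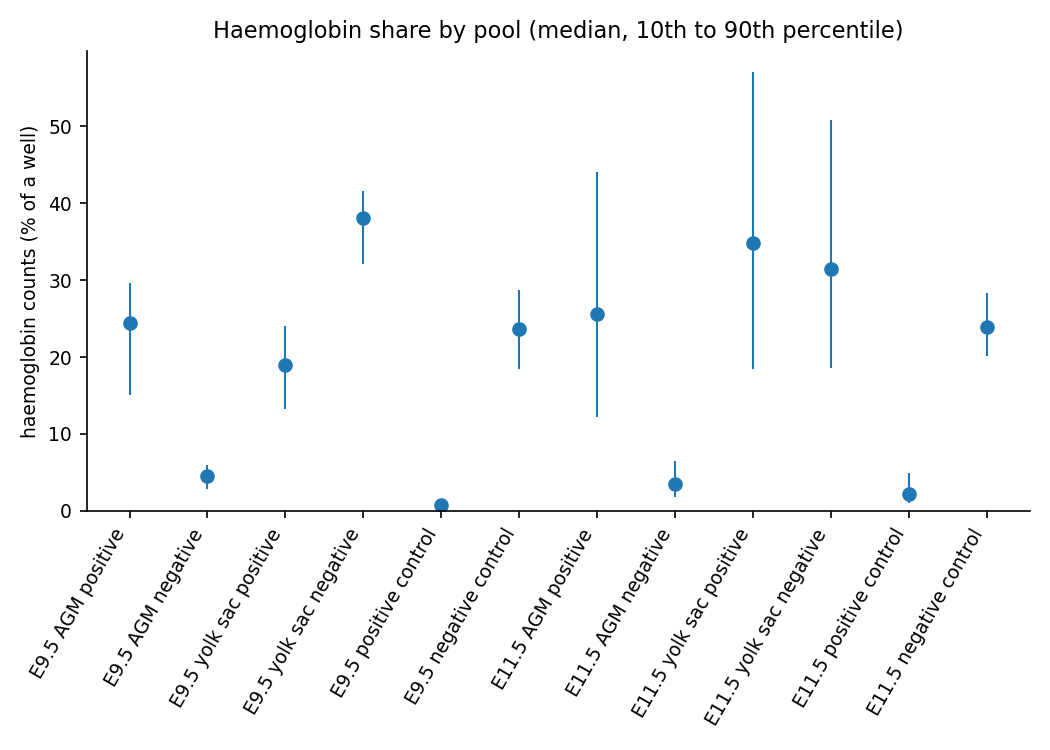
Share of each well's counts taken by haemoglobin genes (vertical axis, percent) in the 8 sorted pools and the control wells of both chips. Points are medians over wells and bars run from the 10th to the 90th percentile; the AGM negative pools lie at 4.54% and 3.44%, the positive control wells at 0.806% and 2.25%.

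The gate comparison asked which genes separate VE-cadherin-positive endothelial cells from the negative microenvironment of the same tissue and stage. Positive pools were higher for a block of endothelial genes in all 4 pairs: the VEGF receptors Kdr and Flt1, the angiopoietin receptor Tek and its partner Tie1, the junction proteins Cdh5 and Pecam1, and Emcn, Cd93, Ramp2, Plxnd1, Stab1 and Rasgrp3. Their smallest log2 ratio over the pairs ran from 3.40 for Tek to 4.60 for Kdr. Negative pools were higher for matrix and mesenchymal genes: the collagens Col1a1, Col1a2, Col3a1, Col5a1 and Col11a1, the proteoglycans Vcan and Gpc3, the growth factor Ptn, the transcription factors Sox5 and Bnc2, the imprinted gene Nnat, and Myl9 of the contractile apparatus. Among these, the log2 ratio nearest to 0 ran from -2.94 for Col11a1 to -1.01 for Myl9.

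Cdh5, which encodes VE-cadherin itself (chromosome 8, 104101625 to 104144511 in GRCm38), checks the sort. Its level was 437 CPM (counts divided by the pool's total and scaled alike for all pools) in the E9.5 AGM positive pool against 14.7 in the negative one, a log2 ratio of 4.89 (4.32 to 5.53). In the E9.5 yolk sac it was 483 against 5.95 CPM, a log2 ratio of 6.34 (5.74 to 7.01). At E11.5 the ratios were 4.97 (4.20 to 5.85) in the AGM and 4.47 (3.79 to 5.25) in the yolk sac. A Cdh5 count was found in 79.1% of the E9.5 yolk sac positive wells and 7.54% of the negative ones, at median depths of 3961 and 12452 counts. At E11.5 the AGM shares were 49.3% and 3.86%, at median depths of 2538 and 2805 counts.

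**Figure D2:**
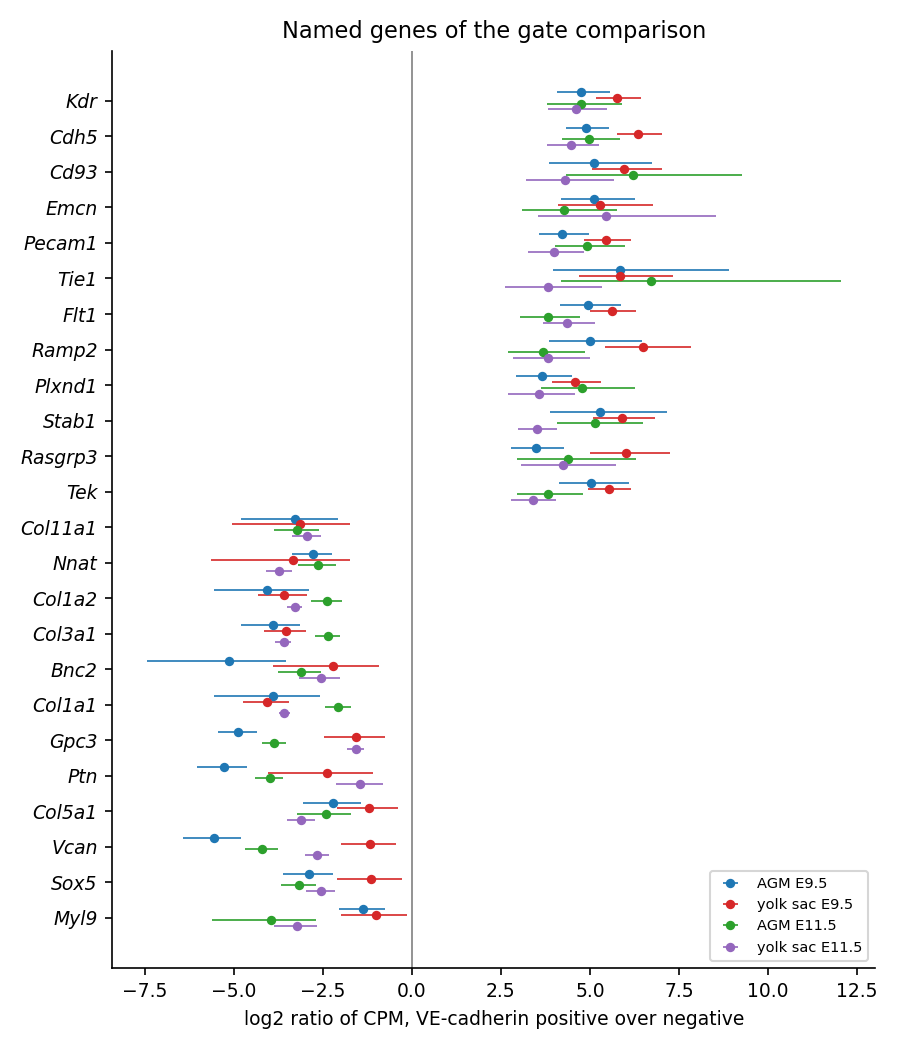
Log2 ratio of CPM, VE-cadherin positive over negative pool (horizontal axis), for the 24 genes named by the fixed rule, with 1 point per tissue and stage and exact 95% counting intervals. Kdr, Cdh5 and the 10 genes listed with them lie at 3.40 or above in all 4 pairs, and the 12 genes from Col11a1 to Myl9 lie at -1.01 or below.

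Of the 12 endothelial markers fixed beforehand, 10 had enough counts in every pair and all 10 were at least 2-fold higher in the positive pools. The median log2 ratio of the list exceeded that of all measured genes by 5.32 in the E9.5 AGM, 5.09 in the E9.5 yolk sac, 5.08 in the E11.5 AGM and 4.03 in the E11.5 yolk sac, above all matched random lists. List values of the comparisons are given relative to that all-gene median here, because it was not 0: in the 4 gate pairs it was -0.38, 0.82, -0.80 and -0.12. Venous genes stood 1.19 to 3.04 above it, with Aplnr and Tek at least 2-fold higher in all pairs, and arterial genes 1.79 to 4.30, with Sox17 and Notch4. The 8 transcription factors of the endothelial-to-haematopoietic transition (Fli1, Erg, Tal1, Lyl1, Lmo2, Runx1, Cbfb and Gata2) stood 1.14 to 2.87 above, and Erg and Runx1 were at least 2-fold higher in all pairs. The haemogenic and emerging blood list stood 1.42 to 3.68 above.

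Mesenchymal markers went the other way, 1.63 to 4.40 below all genes, with 6 of 7 measurable members (Postn, Col1a2, Col3a1, Col1a1, Pdgfra and Col5a1) at least 2-fold lower in the positive pools. Matrix genes as a whole did not: 6 of 19 were lower, none was higher in every pair, and the median was within 0.37 of all genes except in the E11.5 yolk sac, where it lay at -2.01. Erythroid markers differed between tissues, at 2.54 and 3.67 in the AGM pairs but -1.86 and 0.19 in the yolk sac pairs, in the same order as the haemoglobin shares above. Macrophage markers stood at 5.97 in the E11.5 AGM and 3.47 in the E11.5 yolk sac, 2.03 in the E9.5 yolk sac and 0.42 in the E9.5 AGM. Smooth muscle markers were below all genes in the 4 pairs (-0.31, -2.42, -1.78 and -3.77). Notch pathway genes stood 0.22, 3.73, 0.55 and 0.97 above all genes; only Notch4 of 6 measurable members was at least 2-fold higher in every pair. Cell cycle (18 members) and DNA replication (13 measurable members) genes had no member at least 2-fold higher or lower in every pair.

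Among the blood genes named in every comparison, Runx1, the transcription factor needed for blood emergence (chromosome 16, 92601466 to 92826149), was higher in the positive pool of each pair. Its log2 ratios were 4.30 (2.36 to 7.39) and 2.24 (1.80 to 2.68) at E9.5 and 2.71 (2.07 to 3.41) and 1.19 (0.56 to 1.84) at E11.5, AGM before yolk sac. Kit, the stem cell factor receptor, was higher with intervals above 0 in 3 pairs and at 0.52 (-0.25 to 1.29) in the E11.5 AGM. Gfi1b was at 1.33 (0.51 to 2.23) in the E9.5 AGM and -0.34 (-0.79 to 0.09) in the E9.5 yolk sac. The pan-leukocyte gene Ptprc was at 2.92 (1.61 to 4.42), 3.37 (1.66 to 5.75) and 2.54 (1.47 to 3.77) in the E9.5 yolk sac, E11.5 AGM and E11.5 yolk sac. Itga2b, the platelet integrin, was at 2.64 (0.52 to 5.83), 0.85 (0.24 to 1.45), 1.11 (-1.25 to 3.80) and 1.16 (-0.22 to 2.64). Gfi1 had at most 3 counts in a pool at E9.5 and was not analysed here at E11.5.

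The tissue comparison asked how endothelium of the AGM differs from that of the yolk sac on the same chip. Yolk sac positive pools were higher at both stages for scavenger and lymphatic-type genes: Stab2, a hyaluronan receptor of sinusoidal endothelium, Lyve1, a related receptor of lymphatic endothelium and macrophages, and the scavenger receptor Colec12. Gpr182, Adamts5, Fmo1, Ehd3, Hivep3, Col13a1, Npl, Gimap4 and Gpx3 were higher there too. AGM positive pools were higher for the adhesion molecules Cdh2 (N-cadherin), Ptprg and Nrxn3, the mechanosensitive channel Piezo2, the microfibril gene Fbn2, the heparin-binding factor Mdk, and for Zfp462, Rapgef4, Mir99ahg, Dach1 and Skil. Stab2 stood at 939 CPM in the E9.5 yolk sac pool against 16.3 in the AGM, and at 785 against 76.1 at E11.5. The log2 ratios of AGM over yolk sac were -5.85 (-6.41 to -5.34) and -3.37 (-3.76 to -3.00). Lyve1 was at -5.21 (-5.65 to -4.80) at E9.5 and -1.82 (-2.19 to -1.47) at E11.5. Cdh2 was at 2.97 (1.99 to 4.14) and 2.84 (1.85 to 3.99).

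The scavenger and lymphatic-type list lay 5.25 below all genes at E9.5 and 1.09 below at E11.5, under every matched random list; Stab2 and Lyve1 of 7 measurable members were at least 2-fold lower in the AGM at both stages. Endothelial markers had no member of 12 that was at least 2-fold apart at both stages, with list medians of -0.17 and 0.37. Arterial genes (0.18 and 0.14) and venous genes (-0.01 and 0.40) stayed near all genes, and Slc7a7 was the only member of either list at least 2-fold lower in the AGM at both stages. Visceral endoderm markers, which belong to the outer layer of the yolk sac, were lower in the AGM by a median of 3.32 and 4.34, with Apoa1, Afp and Ttr at least 2-fold lower. Mesenchymal markers lay at -1.66 and -1.04, with Col1a1 and Col1a2 lower. These are markers of other cell types, and how their counts came to lie in a VE-cadherin-positive pool was not tested. Ifitm3 was at least 2-fold lower and Atf3 at least 2-fold higher in the AGM at both stages, among the interferon and dissociation stress lists.

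The haemogenic list as a whole and Runx1 stood on opposite sides at the 2 stages, while Itga2b, Ptprc and Gfi1b were below 0 at both, at E11.5 with intervals that include 0. At E9.5 the haemogenic list was lower in the AGM than in the yolk sac, 1.79 below all genes (below every matched random list); at E11.5 it was 0.73 above (above 99.9% of them). Not relative to all genes, its medians were -1.91 and 0.97, and -0.62 and 1.55 with members of at least 100 counts alone. Runx1 and Kit are members of the list: -1.91 and 1.55 are the values of Runx1 itself, and 0.97 is that of Kit. Runx1 stood at 23.1 CPM (44 counts) in the E9.5 AGM and 86.8 CPM (120 counts) in the yolk sac, a log2 ratio of -1.91 (-2.44 to -1.40). At E11.5 it stood at 144 CPM (121 counts) against 49.0 CPM (58 counts), a ratio of 1.55 (1.09 to 2.03). Macrophage markers followed the same order, at -4.01 and 0.83. Itga2b was at -1.97 (-2.97 to -1.07) and -0.89 (-2.73 to 0.69), Ptprc at -3.71 (-6.85 to -1.66) and -0.17 (-0.97 to 0.60), Gfi1b at -0.71 (-1.29 to -0.13) and -0.19 (-2.14 to 1.61), and Kit at -0.33 (-0.77 to 0.10) and 0.97 (0.15 to 1.81). Pecam1 was at -0.25 (-0.47 to -0.04) and 0.83 (0.54 to 1.11), Cdh5 at -0.15 (-0.29 to 0.00) and 0.71 (0.48 to 0.95). With endothelial-like cells alone the E11.5 values were 1.14 (-0.09 to 2.52) for Kit and 0.27 (-0.06 to 0.61) for Pecam1. In wells with at least 3 endothelial markers Kit was at 0.32 (-0.69 to 1.33) and Pecam1 at 0.48 (0.17 to 0.79) at E11.5. The difference between the stages was not tested, and it also lies between the chips.

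**Figure D3:**
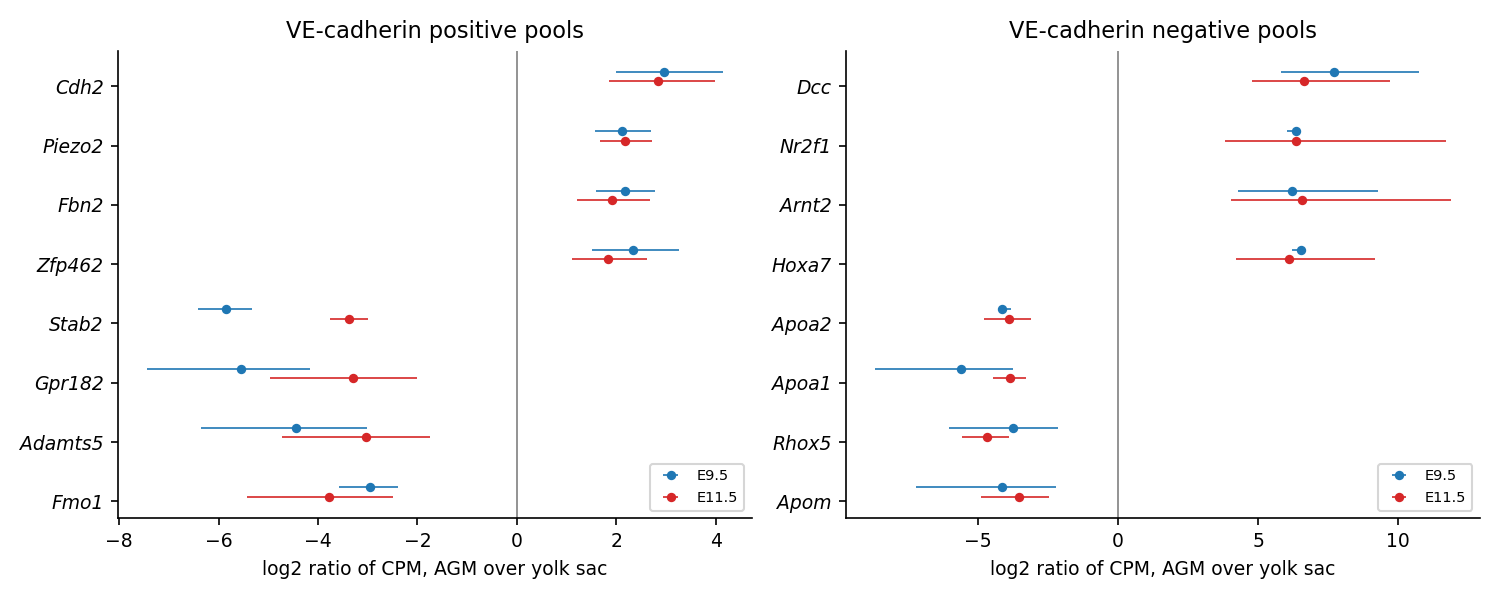
Log2 ratio of CPM, AGM over yolk sac (horizontal axis), for the first 4 genes named in each direction in the positive (left) and negative (right) pools, with 1 point per stage and exact 95% counting intervals; a pool with 0 counts is set to 3 counts and its interval is open on 1 side. Stab2 lies at -5.85 and -3.37 and Cdh2 at 2.97 and 2.84 on the left; Dcc lies at 7.69 and 6.66 on the right.

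In the negative pools the comparison asked how the microenvironments differ. AGM negative cells were higher for genes of trunk mesenchyme and neural tissue: the axon guidance receptor Dcc, the nuclear receptor Nr2f1, the transcription factors Hoxa7, Twist1, Prrx1, Foxp2 and Arnt2, the retinoic acid binding proteins Crabp1 and Crabp2, and Sncaip, Adgrb3 and Lsamp. Yolk sac negative cells were higher for the plasma proteins and lipid carriers that visceral endoderm makes (Apoa1, Apoa2, Apob, Apom, Afp, Ttr and Rbp4), for Rhox5 and S100g, and for the embryonic globins Hbb-bh1, Hba-x and Hbb-y. Crabp1 stood at 424 CPM in the E9.5 AGM against 2.33 in the yolk sac and at 364 against 7.36 at E11.5, log2 ratios of 7.51 (6.57 to 8.64) and 5.63 (4.81 to 6.59). Hoxa7 was at least 93.2-fold higher in the AGM at E9.5, where the yolk sac pool had 0 counts and the floor is 3 counts, and at a log2 ratio of 6.12 (4.23 to 9.19) at E11.5. Apoa1 was at -5.61 (-8.66 to -3.74) and -3.84 (-4.45 to -3.28), and Ttr at -3.92 (-4.93 to -3.06) and -3.52 (-3.96 to -3.10).

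The all-gene median of this comparison was 1.17 at E9.5 and 0.88 at E11.5, where haemoglobin took 38.1% and 31.5% of a yolk sac well's counts. Relative to it, Hox genes of groups 5 to 10 stood 3.56 and 2.87 above, with Hoxa7, Hoxa9, Hoxb6 and Hoxc5 at least 2-fold higher at both stages, and those of groups 1 to 4 stood 4.66 and 1.03 above. Somite and muscle markers stood 5.45 and 3.35 above, with Meox1 and Pax3, and neural markers 4.16 and 1.77, with Map2, Stmn2 and Nes. These lists rest on few members. Measurable at both stages were 4 of 18 Hox genes of groups 5 to 10 and 3 of 12 of groups 1 to 4. For somite and muscle markers it was 2 of 10, and for neural markers 3 of 12. Niche ligands, the secreted factors known to act on blood stem cells, stood 1.06 and 1.14 above: Wnt5a, Ptn, Cxcl12, Mdk, Angpt1, Vegfa and Kitl, 7 of 11 measurable, were at least 2-fold higher in CPM. BMP and TGF-beta pathway genes stood 1.45 and 0.63 above, with Id1, Id2, Id3, Tgfb2, Tgfbr1 and Bmp5 higher. Notch genes were at 2.51 and 0.11, with Notch2, Notch3 and Rbpj higher. Cholesterol synthesis genes were at 0.74 and 0.04. The members called higher in this comparison are not counted relative to all genes. At E9.5 the median gene was itself more than 2-fold higher in the AGM, so a 2-fold ratio alone does not set a member apart.

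On the yolk sac side, 13 of 13 erythroid markers were at least 2-fold lower in the AGM (medians -4.17 and -4.00), as were 8 of 9 measurable visceral endoderm markers (-4.66 and -4.39) and 8 of 9 lipid transport genes (-4.63 and -4.30). Mesenchymal markers split: Twist1, Prrx1 and Pdgfra were higher in the AGM and Col1a1, Lum, Postn, Dcn and Col1a2 in the yolk sac, with medians of -2.15 and -2.74. Smooth muscle markers lay at -2.03 and -2.28, with the visceral smooth muscle actin Actg2 lower in the AGM. Runx1 was at -3.97 (-7.04 to -2.06) at E9.5 and 0.04 (-0.78 to 0.83) at E11.5 in these pools, Gfi1b at -2.39 (-3.19 to -1.67) and -1.23 (-4.53 to 1.17), and Kit at 2.23 (1.27 to 3.27) and 2.27 (1.15 to 3.53). Itga2b was at -3.77 (-6.85 to -1.86) and -0.84 (-3.38 to 1.22), Cdh5 at 1.30 (0.43 to 2.19) and 0.22 (-0.90 to 1.31), and Pecam1 at 0.97 (0.01 to 1.93) and -0.10 (-1.40 to 1.13). These ratios of single genes are not relative to the all-gene medians of 1.17 and 0.88. Ptprc had 0 and 7 counts at E9.5 and 3 and 9 at E11.5. Hba-a1 and Hba-a2 are near-identical, so their single values are uncertain.

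The stage comparison asked what differs between E11.5 and E9.5; stage and chip are the same split here and cannot be told apart from the pools alone. In the positive pools, E11.5 was higher for the macrophage receptor gene Csf1r, the coagulation factor gene F13a1 that macrophages express, the collagens Col1a1, Col1a2 and Col3a1, Gpc3, the steroid enzyme gene Hsd3b6, Pkhd1l1, Neat1, Mir6236, Afp and Pros1. E9.5 was higher for the glycolytic genes Gapdh and Eno1, Ppia, the ferritin gene Ftl1, Ndufb8 of the respiratory chain, Gstp1, Polr2l, Mrpl23, Hapln1, Ahcy, Smim1 and Akr1b3. In the negative pools, E11.5 was higher for the matrix genes Col12a1, Col14a1, Col1a1 and Tnc, the transcription factors Nfia and Nfib, Itm2a, Fkbp7, Egfr, Hsd3b6, Afp and Pros1. Gapdh, Gstp1, Ftl1, Ndufb8, Mrpl23, Eno1, Polr2l, Smim1, Ppia, Dynlt1a, Liph and Nhp2 were higher at E9.5. Csf1r in the AGM positive pools had 88 counts at E11.5 and 1 at E9.5, a log2 ratio of 7.64 (5.12 to 12.96), and was at 2.79 (1.85 to 3.86) in the yolk sac. Nfia was at 4.63 (4.15 to 5.15) in the AGM and 4.25 (3.70 to 4.85) in the yolk sac negative pools, and Col12a1 at 5.14 (4.06 to 6.47) and 6.19 (5.30 to 7.27).

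The positive control wells, which hold the same type of stem cell RNA on both chips, differed for many of these genes in the same direction. Gapdh had 896 counts in the control wells at E9.5 and 10 at E11.5, a log2 ratio of -5.43, beside -5.84 and -5.69 in the AGM and yolk sac positive pools. Eno1 was at -2.88, Akr1b3 at -3.70, Ndufb8 at -2.49 or below (0 counts at E11.5, set to 3), Ftl1 at -1.60, Ppia at -1.54 and Polr2l at -1.33 in these wells. There Pros1 had 4 counts at E9.5 and 1176 at E11.5. Each of these lower genes was at least 2.87 log2 units lower in both positive pools. The control difference falls short of that for Ppia (-1.86 to -1.23) and Polr2l (-2.64 to -0.23), while Ftl1 has a wide interval (-4.00 to 0.16). Of 15 genes named as lower at E11.5 in either gate, 10 had at least 20 counts in the control wells, and 8 of them were at least 2-fold lower there (80%, against 20.2% of all 2830 such genes). Of 20 genes named as higher, 5 could be checked and 3 (Afp, Col1a1 and Pros1) were at least 2-fold higher there. Afp stood at 255 CPM and Col1a1 at 181 CPM in the E11.5 control wells, above 240 and 90.3 CPM in the E11.5 AGM positive pool, so their AGM levels are not above this background; the yolk sac pools lay at 4123 CPM of Afp and 272 of Col1a1. Col1a2, with 13 counts (87.2 CPM) in these control wells, stood at 63.0 CPM in the AGM positive pool and is not above it either, and Col3a1 stood at 99.8 against 80.5 CPM. The stage values of Gapdh, Eno1, Ppia, Ftl1, Gstp1, Akr1b3, Dynlt1a, Polr2l, Mrpl23, Ahcy and Nhp2 are uncertain for a further reason: each has at least 1 processed pseudogene copy with which reads may be shared.

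**Figure D4:**
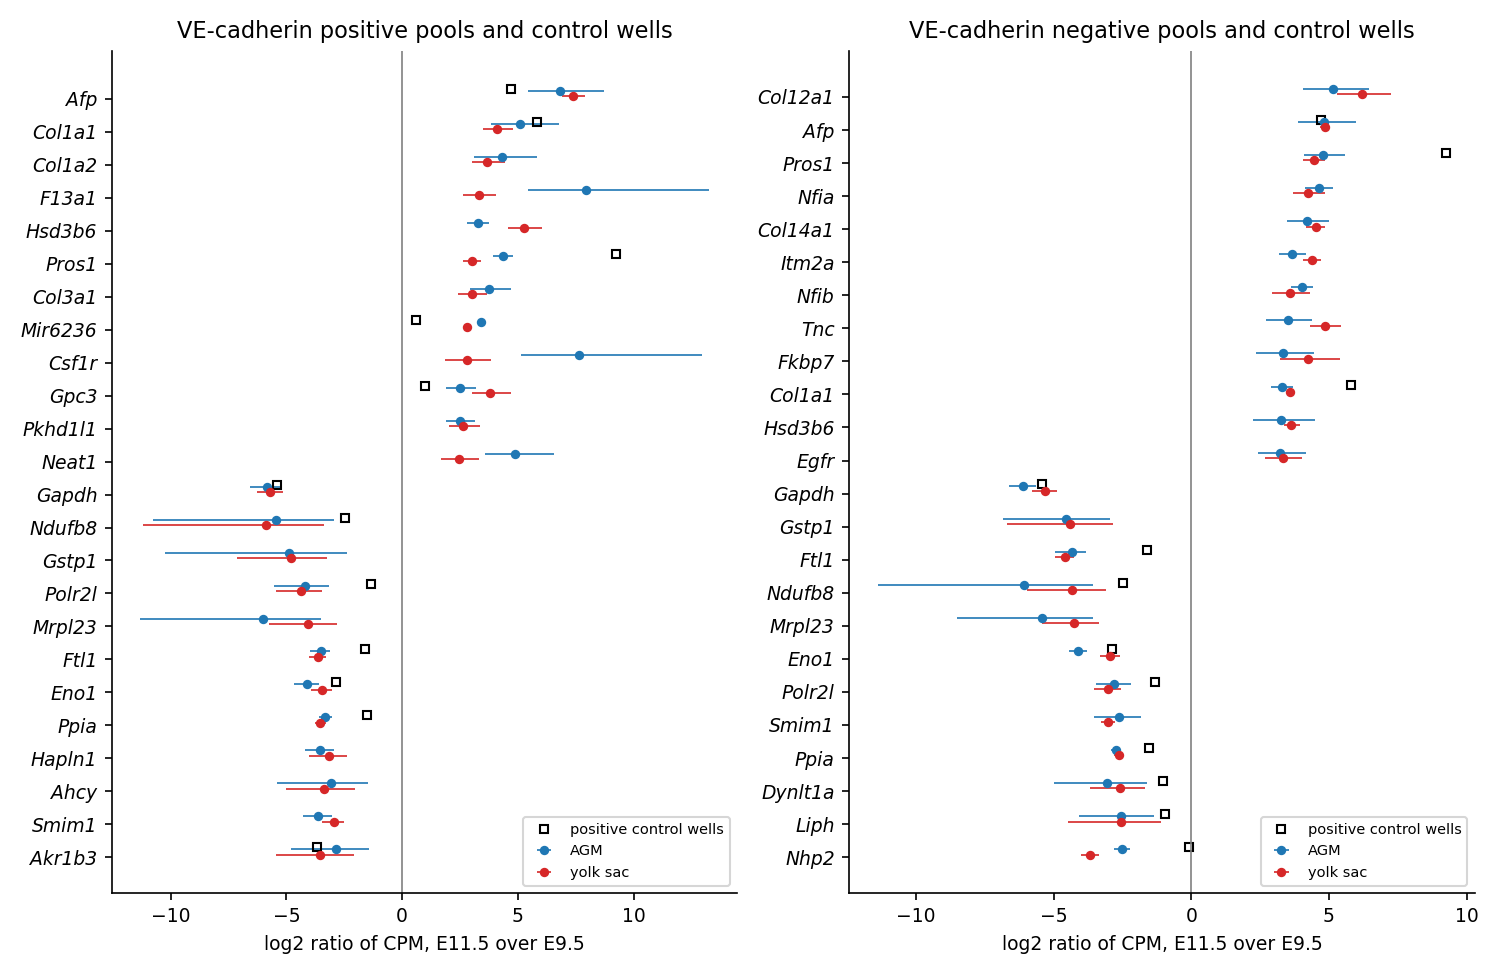
Log2 ratio of CPM, E11.5 over E9.5 (horizontal axis), for the genes named in the positive (left) and negative (right) pools, with exact 95% counting intervals; open squares give the positive control wells where they hold at least 20 counts. Gapdh lies at -5.84 and -5.69 in the positive pools and at -5.43 in the control wells; Pros1 lies at 4.34 and 3.01 in the positive pools and at 9.26 in the control wells.

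Names were therefore chosen again, after the data had been seen, among the protein-coding genes searched for copies. Left out were genes that have a pseudogene copy or that, with at least 20 counts in the control wells, differ at least 2-fold the same way there. Neat1 and Mir6236 dropped out only because they are not protein-coding. With the first choice, 9 of 24 names in the positive and 11 of 24 in the negative pools were shared. In the positive pools the second choice added Pf4, the platelet chemokine, with Il31ra, Selenow, St6galnac3 and Hdac9 at E11.5. On the E9.5 side Hapln1 and Smim1 stayed and Asns, Gart, Enpp6, Pycrl, Alad, Aimp2, Prkar2b, Nxpe2, Cd3eap and Ppa1 were added. Genes with fewer control counts could not be left out this way: Col1a2 (0 and 13 counts at E9.5 and E11.5), Col3a1 (0 and 12), Il31ra (5 and 13), Selenow (0 and 5), Pycrl (15 and 1), Cd3eap (17 and 1) and Alad (17 and 0) differ in the control wells in the same direction. So do Nfia (2 and 7, a log2 ratio of 2.87, 0.47 to 6.17), Itm2a (1 and 6), Cd44 (1 and 5), Col14a1 (0 and 5) and Tnc (0 and 4) of the negative pools. Pf4 was at 4.98 (3.96 to 6.23) in the AGM and 2.22 (1.84 to 2.61) in the yolk sac, and Hapln1, a linker of hyaluronan matrix, at -3.54 (-4.19 to -2.95) and -3.16 (-4.04 to -2.40). In the negative pools the second choice added Col11a1, Nrk and Cd44 at E11.5 and Dqx1, Noc2l, Alad, Hemgn, Hbb-bh1, Timm50, Timm10, Gnb1l, Nubp1 and Aimp2 at E9.5.

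Relative to all genes (medians of -0.33 and -0.68 in the positive and 0.09 and 0.35 in the negative pools, AGM before yolk sac), the macrophage list stood 5.78 and 1.19 above in the positive pools, with Csf1r and C1qb at least 2-fold higher at E11.5 in both tissues. The haemogenic list stood 2.12 above in the AGM and -0.28 in the yolk sac, with Ptprc and Spi1 higher and Gfi1b lower in both. At E11.5 Runx1 had a count in 58 of the 99 macrophage-like wells but in 7 of 138 and 0 of 90 wells of the endothelial-like clusters. The macrophage-like cluster also had raised granulocyte and haematopoietic progenitor markers, so these Runx1 counts need not come from macrophages. With endothelial-like cells alone the log2 ratio in the AGM, not relative to all genes, was 0.58 (-0.18 to 1.13) for the haemogenic list against 1.79 with all wells, 0.97 (0.16 to 1.68; 4 members) for the macrophage list against 5.45 (11 members), and 0.63 (-0.40 to 1.56; 13 and 40 counts) for Runx1. In wells with at least 3 endothelial markers, which need not lie in these clusters, the values stayed higher at 1.28 (0.72 to 1.80), 4.42 (3.66 to 5.33) and 1.95 (1.27 to 2.62). With all wells, Runx1 was at 2.64 (2.13 to 3.17) in the AGM and -0.83 (-1.30 to -0.36) in the yolk sac, and Ptprc at 4.76 (2.75 to 7.89) and 1.22 (0.39 to 2.10). Gfi1b was at -2.09 (-3.77 to -0.76) and -2.61 (-3.89 to -1.53), Kit at -0.41 (-1.03 to 0.18) and -1.71 (-2.44 to -1.04), and Itga2b at -0.31 (-2.14 to 1.25) and -1.40 (-2.42 to -0.47). Cdh5 was at -0.12 (-0.31 to 0.06) and -0.98 (-1.18 to -0.78), and Pecam1 at 0.40 (0.16 to 0.64) and -0.68 (-0.95 to -0.42). These 2 depend on which wells are used: in wells with at least 3 endothelial markers Cdh5 was at 0.66 (0.46 to 0.86) and -0.07 (-0.30 to 0.15) and Pecam1 at 1.14 (0.89 to 1.40) and 0.38 (0.10 to 0.65). Both genes are among the 12 markers that choose these wells. The choice keeps 126 of 284 AGM and 128 of 343 yolk sac wells at E11.5, against 281 of 299 and 287 of 325 at E9.5. Part of the shift of Cdh5 and Pecam1 thus follows from the choice itself. Mesenchymal (4.80 and 4.15), visceral endoderm (4.24 and 6.07) and lipid transport genes (4.23 and 6.07) were higher at E11.5 in these endothelial pools, with the limit that the AGM levels of Afp, Col1a1 and Col1a2 are not above the control wells. Scavenger genes were at 2.38 and 0.16, and endothelial markers at 0.02 and -0.28, with Cldn5 at least 2-fold lower. Haemoglobin genes of the embryo were at -0.38 and 0.57, and the adult genes Hba-a1 and Hba-a2 at 0.99 and 2.18.

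In the negative pools, matrix genes stood 1.48 and 2.91 above all genes, with 15 of 21 measurable members at least 2-fold higher at E11.5, among them Col1a1, Lum, Postn and Sparc. Mesenchymal markers (1.85 and 3.15, 8 of 9), smooth muscle markers (1.79 and 3.09, with Actg2, Acta2 and Myh11), niche ligands (1.22 and 1.41, 8 of 11, among them Igf1, Igf2, Cxcl12 and Dlk1) and BMP and TGF-beta genes (1.29 and 1.88, 6 of 9) were higher too. Dissociation stress genes, which respond to tissue handling, stood 1.72 and 2.39 above, with 8 of 12 at least 2-fold higher, among them Fos, Egr1 and Junb; in the positive pools they stood at 1.98 and 1.31. Fewer genes per well and a higher mitochondrial share go with the same split, so handling and stage cannot be told apart here. DNA replication genes had medians of -0.87 and -0.76 in the positive pools, with 9 of 14 at least 2-fold lower at E11.5, among them Tyms, Mcm5 and Gins2. In the negative pools the medians were -0.75 and -1.64, and Mcm2 and Mcm5 of 13 measurable members were at least 2-fold lower in both tissues. These counts of members are not relative to all genes, so they cannot be compared between the gates; the positive pool median nearest 0, also not relative, was -1.20, and -0.68 with totals that leave out haemoglobin, mitochondrial genes and Gm42418. Glycolysis genes were at -1.20, -0.59, -1.47 and -1.36. Among the blood genes, Runx1 was at 4.22 (2.21 to 7.35) in the AGM and 0.22 (-0.40 to 0.83) in the yolk sac negative pools, Gfi1b at -2.45 (-5.61 to -0.37) and -3.61 (-4.94 to -2.54), and Kit at 0.64 (-0.15 to 1.43) and 0.61 (-0.78 to 1.92). Itga2b was at 1.22 (-1.90 to 4.81) and -1.71 (-2.98 to -0.64), and Ptprc at 1.61 (0.01 to 3.27) in the yolk sac, with 3 and 0 counts in the AGM. Cdh5 was at -0.20 (-1.25 to 0.80) and 0.89 (-0.08 to 1.84), and Pecam1 at -0.29 (-1.55 to 0.89) and 0.78 (-0.24 to 1.78). In the control wells the DNA replication list had a median log2 ratio of -0.37 with 11 of 12 members below 0, and the glycolysis list -0.66 with 10 of 11 below 0. These control values are not relative to all genes. The median there was -0.41 for 1913 genes without a pseudogene copy and -0.17 for 738 genes with one. The DNA replication value is thus near that of genes without a copy.

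Haematopoietic progenitor genes stood 1.63 to 3.80 above all genes between the gates, with Cd34 and Runx1 at least 2-fold higher in all positive pools. Granulocyte or mast cell genes stood 5.56 above between the gates of the E11.5 AGM, from 4 members whose counts lie in few wells: the 2 wells with most held 78 of 125 counts of Mpo, 27 of 40 of Prtn3, 39 of 98 of Srgn and 32 of 36 of Cpa3. Megakaryocyte genes stood 4.82 above there, from 2 members. In the tissue comparison of the negative pools, from at most 4 members each, mesonephric epithelium genes lay at -1.30 and -3.20, coelomic epithelium genes at -1.50 and -2.49, gut epithelium genes at -1.18 and -4.30, neural crest genes at 1.60 and -0.53 and germ cell genes at 2.47 and -2.49. Interferon genes stood 1.60 and 0.25 above all genes in the stage comparison of the positive pools and 0.40 and 1.79 in the negative pools. Cell cycle genes lay at -0.49 and -0.34 in the stage comparison of the positive pools, with Ccnb1, Aurka, Cdc20, Plk1 and Birc5 at least 2-fold lower at E11.5.

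Cell class shares were read from clusters made for each stage, 10 at E9.5 and 9 at E11.5, named from fixed markers; the number of markers a name needs was set after the data had been seen. Most clusters held cells of 1 pool, so a cluster may reflect that library rather than a cell type. At E9.5, endothelial-like clusters held 285 of 299 AGM positive wells (95.3%, 92.3% to 97.4%) but 3 of 325 yolk sac positive wells (0.923%). The other 322 yolk sac positive wells fell in a pair of clusters left unnamed by the rule: their leading genes were Lyve1, Rac2, Ifitm3, Gpr182 and Runx1 in 1 and Stab2, Mrc1, Cd36 and Maf in the other, and 10 and 11 of the 12 endothelial markers were raised in them. The endothelial-like share is therefore not compared between tissues at E9.5, and it moved with the settings: the AGM share was 49.5% at resolution 2, 77.9% and 63.9% with 1000 and 4000 variable genes, 51.2% with no filter, 41.6% with the strict filter and 64.1% without doublets, and the yolk sac share 56.9% with the stages clustered together. Negative AGM wells were mesenchymal-like (354 of 354). Of the yolk sac negative wells 208 mixed visceral endoderm, mesenchymal and erythroid genes and stayed unnamed, and 97 of 305 (31.8%, 26.6% to 37.4%) were mesenchymal-like. The cluster of these 97 wells was mixed too. It had raised erythroid, visceral endoderm and megakaryocyte markers and a median haemoglobin share of 34.2%, but its leading genes gave it the mesenchymal name. With 1000 variable genes 0 of the 354 AGM wells took that name; the yolk sac share was 100% at resolution 0.5, 6.56% with 1000 variable genes and 0% with the stages together.

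At E11.5, 133 of 284 AGM positive wells (46.8%, 40.9% to 52.8%) and 95 of 343 yolk sac positive wells (27.7%, 23.0% to 32.8%) were endothelial-like, in separate clusters for each tissue. A macrophage-like cluster with Lyz2, Tyrobp, C1qb and C1qc held 55 AGM positive wells (19.4%, 14.9% to 24.4%) and 41 of 343 yolk sac positive wells (8.72% to 15.9%), and 3 wells of the negative pools. It was mixed: S100a8 came first among its leading genes. Granulocyte or mast cell markers (Mpo, S100a8, S100a9 and Srgn) and progenitor markers (Runx1, Spi1, Kit and Ikzf1) were raised in it too. Erythroid-like wells made up 83 of the AGM positive pool (29.2%, 24.0% to 34.9%) and 2 of the yolk sac positive pool, where 179 wells (52.2%) lay in an unnamed cluster of red cell and visceral endoderm genes. This contrast turned with the settings: 184, 169 and 142 yolk sac positive wells were erythroid-like at resolution 0.5, at resolution 2 and with 4000 variable genes, where the AGM share was 31.0%, 31.0% and 2.46%, and the other settings gave no erythroid-like cluster. Visceral endoderm-like wells numbered 14 in the positive and 9 in the negative yolk sac pool, and 52.8% and 50.9% of these pools stayed unnamed. Clustering both stages together left 0 of these wells in an endothelial-like cluster, no filter left 2 of 388 yolk sac positive wells there, and under the strict filter no E11.5 cluster was endothelial-like and 53 of 77 AGM positive wells were granulocyte-like or mast cell-like, so these shares depend on the settings.

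The 8 transcription factors of the endothelial-to-haematopoietic transition were also counted within single wells, thinned to 2000 counts so that total counts were equal; haemoglobin still takes a different part of them in each pool. No well had a count of at least 6 of the 8, which allows shares of up to 1.24%, 1.15%, 1.77% and 1.14% of the 296 AGM and 319 yolk sac positive wells of E9.5 and the 207 and 321 of E11.5 that were deep enough. These limits bound the detection of the set at this depth, not its co-expression, since few factors are seen per well. The mean number of factors per well was 0.760, 0.900, 0.787 and 0.570 in these pools, against 0.266, 0.201, 0.424 and 0.228 in the negative pools. The negative pools are not a baseline without the set. Without thinning, Tal1 was in 62.0%, Lyl1 in 18.0% and Lmo2 in 14.4% of E9.5 yolk sac negative wells. Their mean was then 1.34 factors, against 1.68 in the yolk sac positive pool, at median depths of 12452 and 3961 counts. Without thinning, 3 E9.5 AGM positive wells, 1 E9.5 yolk sac positive well and 1 E9.5 yolk sac negative well had at least 6. Wells with Runx1, Gfi1 or Gfi1b (Runx1 or Gfi1b alone at E11.5) made up 11.1% (7.80% to 15.3%), 15.4% (11.6% to 19.8%), 16.4% (11.7% to 22.2%) and 9.03% (6.13% to 12.7%) of the thinned positive pools. In the negative pools the shares were 3.11%, 13.2%, 4.80% and 3.85% (E9.5 yolk sac negative wells without thinning 56.4%, at a median of 12452 counts). The E9.5 yolk sac shares differ by gene: Runx1 was in 10.3% of positive and 2.96% of negative wells, Gfi1b in 5.02% and 10.5%.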

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

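All tests in this part were chosen after the results they weigh had been seen, and each set of tests weighs a pattern on the data in which it was found.

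Runx1, Pecam1 and the median of the haemogenic list stood on opposite sides between AGM and yolk sac positive pools at the 2 stages, but not every blood gene did. The difference between the stages was not tested. The list median at E9.5 is the value of Runx1 itself, a member of the list. Pecam1 at E11.5 stayed above 0 in each choice of wells, but its size changed. It was at 0.83 (0.54 to 1.11) with all wells and 0.48 (0.17 to 0.79) in wells with at least 3 endothelial markers, of which it is 1. With endothelial-like cells alone it was at 0.27 (-0.06 to 0.61), an interval that includes 0. The log2 ratio of AGM over yolk sac was higher at E11.5 than at E9.5 by 3.46 for Runx1, by 2.88 for the haemogenic list and by 1.08 for Pecam1; list values in this part are not relative to all genes. Control wells drew attention for another reason, counts of genes they were not meant to hold: Hbb-y had 453 counts in the negative control wells of E9.5 and 2403 in those of E11.5, and Pros1 had 1176 counts in the positive control wells of E11.5.

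Weighed against a change in which cells the positive pools hold, the haemogenic list had a median of -1.39 (-1.71 to -0.60) at E9.5 and 1.08 (0.27 to 1.46) at E11.5 without wells holding at least 3 macrophage markers. At E11.5 the summed macrophage markers then went from 0.57 to -0.26, which argues against macrophages as the whole cause there, but at E9.5 they went only from -3.89 to -3.41, so macrophages stay open. In wells with at least 3 endothelial markers the list was at -1.86 (-2.39 to -1.38) at E9.5, where this kept 281 of 299 and 287 of 325 wells and so tests little; at E11.5 these wells gave 0.66 (-0.10 to 1.18), with Runx1 at 1.09 (0.26 to 1.95), and endothelial-like cells alone 1.14 (0.16 to 1.61; 3 members), with Runx1 at 3.45 (0.71 to 8.86; 13 against 1 counts). The last values go against a different endothelial share at E11.5, but rest on too few members and counts to exclude it. The tissue difference named by the design, and the chip that goes with each stage, stay open as well and could not be tested.

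Haemoglobin counts were present in all 2626 kept wells, AGM negative ones included. Wells with another erythroid gene held 1.16 times the haemoglobin share of the other wells of their pool, as a median over pools. This does not exclude red cells in most wells, since most wells of 7 pools held another erythroid gene (305 of 305 in the E9.5 yolk sac negative pool, but 90 of 337 in the E11.5 AGM negative pool) and the others may have missed it. Positive control wells held at most 0.29 of the median haemoglobin count of 7 pools, so carry-over over the chip is too small for these, but 0.794 of that of the E11.5 AGM negative pool, whose haemoglobin may be carry-over. The share of Hbb-y among embryonic haemoglobin counts differed by at most 1.03 points between endothelial wells and other wells of a positive pool, consistent with free RNA from 1 source in each suspension, though red cells of that suspension in the wells would give this too.

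Of the genes named as lower at E11.5 and checkable in the positive control wells, 80% were at least 2-fold lower there too (20.2% of all 2830 checkable genes). A difference between the chips may thus account for part or all of their difference. Nhp2 at -0.08 (-0.36 to 0.19) and Liph at -0.94 (-2.38 to 0.29) were not 2-fold lower there. Both were at least 2.52 log2 units lower in both negative pools. For genes named as higher the share was 60%, against 4.03% of all checkable genes, but from 5 genes. Among them, Afp and Col1a1 also had 31 and 9 counts in the E11.5 negative control wells. Their counts in the positive control wells therefore need not come from the stem cell RNA. For the genes named as higher a difference between the chips stays open. Reads shared with pseudogene copies cannot be told apart from this: 73.3% of the lower genes have a copy. Among all searched genes eligible for these names, 26.6% in the positive and 29.6% in the negative pools have one. Yet in the control wells genes with at least 10 copies stood 0.50 above genes without one, the opposite of what such sharing alone would give. Stage and chip are the same split, so they cannot be told apart for a gene not measured in the control wells. A stage difference also stays open for genes that differ less in these wells than in the pools, such as Nhp2.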

How the results depend on the processing

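Of 204 values of the main results under an alternative, 170 stayed within their counting interval or 1.5 times their count, 34 moved and 0 reversed. Part of these outcomes were fixed in advance. No thinned well can hold 7 factors where no well holds 6. Leaving out a pair other than the one nearest 0 returns the main value, and shares and counts of names cannot reverse. Results that an alternative could not give are not among the 204 values. Under the strict filter no E11.5 cluster was endothelial-like. Its endothelial-like shares are therefore missing from the count rather than counted as moved (21 values, against 23 with no filter). Of 1008 values of named genes, 903 stayed, 105 moved and 0 reversed. The sort check and the genes named by the size of their ratio kept their direction under every alternative run. Other values between tissues at E11.5 did not: Ptprc went from -0.17 to 0.75 with endothelial-like cells alone, Gfi1b from -0.19 to 0.83 in wells with 3 endothelial markers, all with intervals that include 0, and the macrophage list from 1.07 to -2.29, from 1 member, with endothelial-like cells alone. Between stages, wells with 3 endothelial markers took Cdh5 of the AGM positive pools from -0.12 to 0.66 and, in the yolk sac, Pecam1 from -0.68 to 0.38 and the scavenger list from -0.52 to 0.50. Cdh5 and Pecam1 are themselves among the markers that choose these wells, so part of their shift follows from the choice. Endothelial-like cells alone took Kit of the AGM from -0.41 to 0.13 and the 8 transition factors from -0.33 to 0.27. For the values below the cause was not tested. No analysis paired by replicate number was made because the labels carry none; the pools matched by tissue and stage were compared pair by pair, and a test over the 4 gate pairs, which the design allows, was not run. Endothelial-like cells alone gave no value for pairs with the E9.5 yolk sac positive pool, which holds 3 such cells where at least 20 were required. The totals without Gm42418, the wells with 3 endothelial markers and the names chosen again were chosen after seeing the data.

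List medians are given as the log2 ratio of the pair nearest 0, or of the stage named, not relative to all genes; with the main settings they were 3.91 for endothelial and -2.43 for mesenchymal genes between gates, -0.85 for scavenger genes at E11.5, -1.91 and 0.97 for the haemogenic list, 2.02 for niche ligands and -1.20 for DNA replication. With the strict filter the endothelial list between gates was at 4.69, scavenger genes between tissues at E11.5 at -1.13 and DNA replication genes between stages at -0.82. TMM scaling gave -1.82 for mesenchymal genes between gates, -1.09 for scavenger genes, 1.10 for niche ligands between tissues and -0.99 for DNA replication. Totals without haemoglobin and mitochondrial genes gave -2.01, -1.08, 1.48 and -0.99 for the same lists, and also without Gm42418 -1.81, -1.09, 1.34 and -0.68. Named classes alone gave 4.98 for the endothelial list and -2.29 for scavenger genes, which were at -1.85 in wells with 3 endothelial markers. Members with at least 100 counts gave -0.62 at E9.5 and 1.55 at E11.5 for the haemogenic list. Leaving out 1 pair gave 3.91 to 4.28 for endothelial, -3.47 (without the E11.5 AGM) to -2.43 for mesenchymal, 2.02 to 2.23 for niche, -1.44 to -1.20 for DNA replication and 1.56 to 3.27 (without the AGM) for matrix genes.

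Names of protein-coding genes without pseudogene copies and control differences shared 9 and 11 of 24 genes with the first choice in the positive and negative pools. The endothelial-like share of the E11.5 AGM positive pool was 0% with the stages clustered together and 36.3% with no filter; that of the yolk sac was 0% and 0.515%, and 36.2% with 4000 variable genes. The macrophage-like share of the AGM positive pool was 14.4% at resolution 2, 10.6% with 1000 variable genes, 14.2% with no filter and 26.0% with the strict filter, and 26.0% in the yolk sac with the strict filter. Shares of wells with a count are limited by the depth of the E11.5 positive pools, medians of 2538 and 3008 counts.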

Other observations

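The tests named in this part were chosen after the values had been seen. A small set of 5 wells of the E11.5 AGM positive pool stood apart by neutrophil granule genes. Their summed counts of S100a8, S100a9, Ngp and Camp were 1448, 704, 479, 472 and 343, against 7 in the next well. These wells lay in the VE-cadherin-positive sort, and no explanation was tested.

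A cluster of 23 E11.5 yolk sac wells, 14 from the positive and 9 from the negative pool, was led by the endocytic receptors Cubn and Lrp2, with Afp, the clotting genes Fgb and F2, Apob and Ttr, and detected 11 visceral endoderm markers.

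Cdk8 took 13121 counts in the positive control wells of E9.5 and 5656 in those of E11.5, 42247 and 37939 CPM. Afp and Col1a1 had 38 and 27 counts in the E11.5 positive control wells, and Hba-x had 794 and 322 counts in the positive control wells of E9.5 and E11.5. Gm42418 was not used as a named gene.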
